A study of Mus musculus with 24 samples.

How the data were processed

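Total RNA from mouse digits of the strains C57BL/6 (B6) and MRL/MpJ (MRL) was measured on Affymetrix exon arrays at days 0, 3, 7 and 14 after surgical amputation, day 0 being the unamputated digit. The labels gave 3 biological replicates for each of the 8 groups of strain and day, 24 arrays in all. They named the tissue as the second phalanx of the hindlimb middle digits, while a free-text note on the arrays named the anterior part of that digit; which description holds for the RNA is not given in the sources used here. Per the labels, the authors summarised the arrays with RMA (background correction, quantile normalization and median-polish summary of probes) in Affymetrix Expression Console, with the mm8 mouse genome as the build. The deposited values are summarised intensity values per probe set on a linear scale, from 3.99 to 12789. How they were turned to a linear scale is not given in the sources used here. The array medians ran from an intensity of 141 to 181, a step of 0.356 in log2, so the arrays were not on 1 common distribution.

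The table held 16661 probe sets. Of these, 14939 were paired with 1 gene symbol, 989 with several and 733 with none. The 15928 probe sets with at least 1 symbol were tested. By Entrez identifier, 14884 of the single-symbol probe sets matched the reference gene table of assembly GRCm38.p6, 55 did not, and 0 symbols were changed by the match. No coordinates are printed, since that assembly is not the build of the arrays. For gene lists and named genes, 1 probe set per gene was used, the one with the highest mean over the 24 arrays, which gave 14807 genes. A list symbol absent from the array was matched by a synonym only where it was not itself a current gene symbol. A further 8 probe sets named a keratin among several symbols and were left out of the lists.

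The deposited values were turned to log2. One limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes) held 1 mean for each of the 8 groups. It had 16 residual and 4.62 prior degrees of freedom. Contrasts of the group means gave MRL minus B6 on each day, each later day minus day 0 within each strain, the difference between the strains in those changes, and the mean of days 3, 7 and 14 minus day 0 over both strains, 14 comparisons in all. Another 12 comparisons were added after the values had been seen, such as day 14 minus day 7 and contrasts that set the groups labelled MRL day 0 and MRL day 3 in each other's place. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Errors of log2 differences are the moderated standard errors (SE) of limma, and errors of group levels are the standard deviation (SD) over 3 arrays. With 3 arrays against 3, an exact permutation test cannot give a p below 0.1, so the number of arrays limits the precision of every value.

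Gene lists were fixed before the data were examined, 35 in all, of gene families and of markers of cell types that a digit may hold. Each list was tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated from the data, and with fry, and the p-values were adjusted over the lists of a comparison. The keratins are named in the title of the series and may have been picked on these arrays, so their list is not independent evidence. A further list of 16 hair follicle genes that are not keratins, 14 of them measured, was written after the data had been examined. The rule for named genes was also fixed before the data were examined. It took the 10 highest and the 10 lowest log2 differences among genes that passed the test with no overlap between the arrays of both groups, with the adjusted p alone for the contrasts over more than 2 groups. It also took each keratin and up to 4 members of each list with the largest changes. Predicted genes were left out of the text.

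The fit was tested on simulated data with 15928 simulated probe sets of the same design. For MRL minus B6 at day 7 it recovered 61.2% of simulated changes of 0.5 in log2, 92.5% of changes of 1 and 100% of changes of 2, with 3 false calls. For day 3 minus day 0 in B6 the shares were 47.8%, 95.5% and 95.5%, with 7 false calls. For the strain difference in the day 14 change they were 13.4%, 82.1% and 100%, with 5 false calls. The simulated errors were independent between probe sets, without scaling steps between arrays, and a small part of the probe sets was changed. These shares and false calls may therefore not hold for the real arrays.

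The labels gave no batch. Replicate numbers were examined as possible pairs, and the correlation of residuals between arrays of the same number was above 0.1 in 10 of 84 cases. It was above 0.1 for all 3 numbers in 1 of 28 pairs of groups, B6 day 0 with MRL day 14. Both enter the strain difference in the day 14 change. The arrays were treated as unpaired, and a replicate block was run as an alternative. The alternatives fixed before the data were examined were cyclic loess scaling, array weights, a variance trend with robust hyperparameters, a filter on dim probe sets, all probe sets of the table, only the arrays compared, a replicate block, all probe sets of a list's genes, an estimated correlation in camera and leaving out each array in turn. Leaving out the arrays labelled MRL day 0 and MRL day 3, setting these groups in each other's place, and using B6 alone in the contrast of amputated and unamputated digits were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.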

Results

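Gene expression was measured in the digits of 2 mouse strains after amputation. B6 is a common laboratory strain, and MRL is a strain known for the closure of ear wounds. Each strain was sampled before amputation (day 0) and on days 3, 7 and 14 after it, with 3 arrays per group. The series sets regenerating against unamputated digits and, by its title, is about keratin genes in both strains. Differences are in log2 with the standard error (SE) or in fold, and levels are log2 means with the standard deviation (SD) over 3 arrays. Signal over background was not analysed here, so folds against low levels hold an unmeasured background. For the largest changes named between 2 groups, all 3 arrays of one group lay above all 3 of the other.

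Il1b and Mmp13 stood high in the arrays labelled MRL day 0 and low in those labelled MRL day 3, the reverse of B6. Il1b, the cytokine interleukin 1 beta, had a log2 level of 6.01 ± 0.38 (SD, n = 3) in B6 day 0 and 11.78 ± 0.10 in B6 day 3. It stood at 10.21 ± 0.14 in the arrays labelled MRL day 0 and at 5.98 ± 0.80 in those labelled MRL day 3. Mmp13, a collagenase of bone and cartilage, gave 6.01 ± 0.31 and 10.99 ± 0.35 in B6, against 10.54 ± 0.82 and 5.82 ± 0.18 in MRL as labelled. The hair keratin Krt31 went from 10.60 ± 0.21 to 6.38 ± 0.12 in B6, and from 7.48 ± 0.40 to 10.13 ± 0.14 in MRL as labelled. On an axis over 912 probe sets, with B6 day 0 near 0 and B6 day 3 near 1, the 3 arrays labelled MRL day 0 lay at 0.715 to 0.761. The 3 labelled MRL day 3 lay at 0.0869 to 0.170. H2-Ea, an MHC class II chain that the B6 haplotype does not transcribe, kept to the strain, at 11.31 ± 0.08 and 11.11 ± 0.27 in these MRL groups and 5.24 ± 0.13 in B6 day 0. The comparisons that use the arrays labelled MRL day 0 or MRL day 3 are therefore given last and as labelled.

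**Figure D1:**
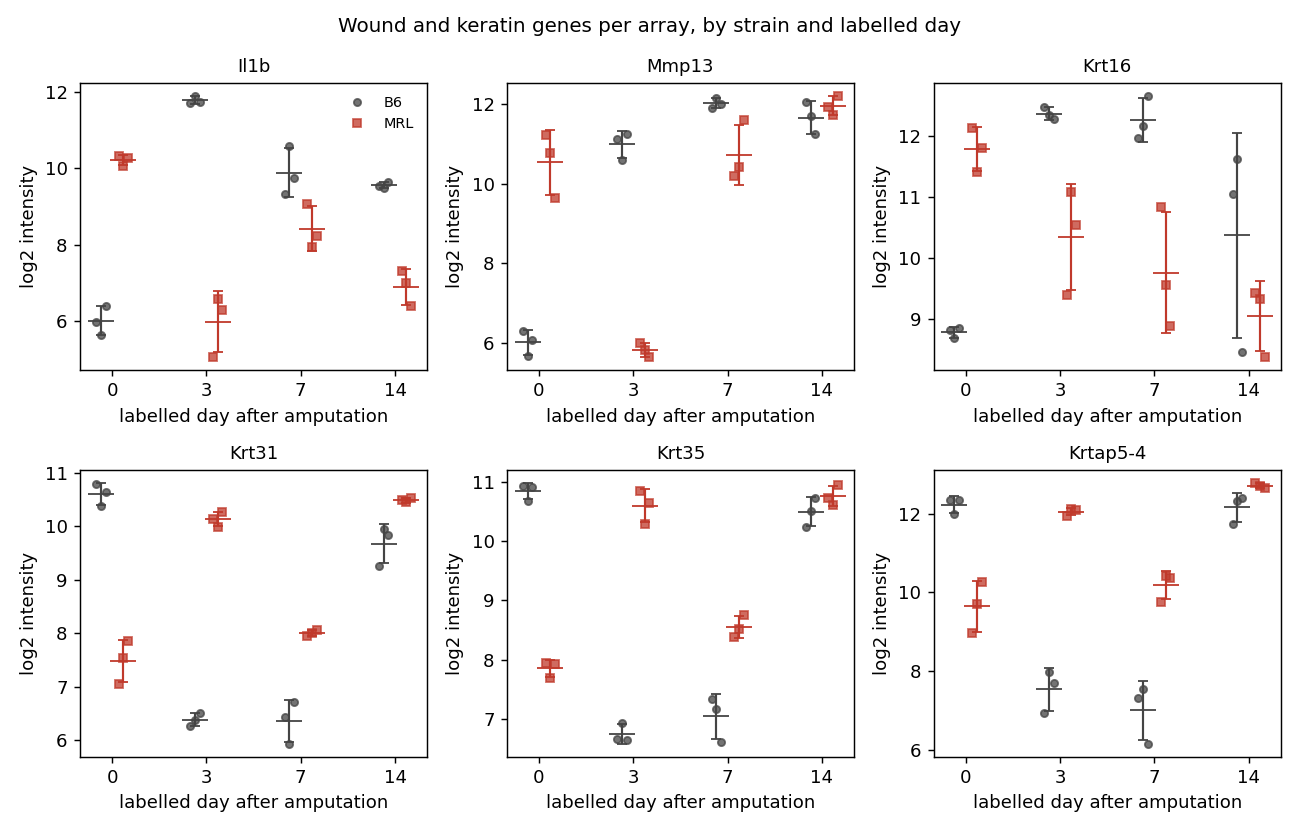
Log2 intensity of 6 genes in each array (points) by labelled day after amputation, for B6 and MRL, with the mean and bars of 1 SD over 3 arrays. Il1b, Mmp13 and Krt16 stood high, and Krt31, Krt35 and Krtap5-4 low, at B6 day 3 and in the arrays labelled MRL day 0.

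**Figure D2:**
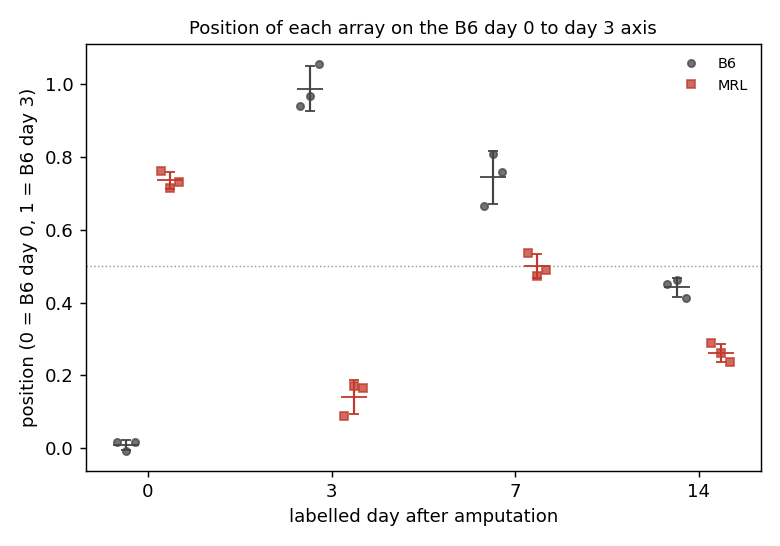
Position of each array (points) on the axis from B6 day 0 to B6 day 3 over 912 probe sets, by labelled day, with the mean and 1 SD over 3 arrays. The arrays labelled MRL day 0 had a mean of 0.736 and those labelled MRL day 3 a mean of 0.140, on either side of the dotted midpoint.

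By day 3 after amputation in B6, several chemokines, neutrophil genes and matrix proteases had risen and the keratins of hair and nail had fallen. Ccl3, a chemokine that draws in monocytes and neutrophils, rose 85.3-fold, from 5.66 ± 0.30 to 12.07 ± 0.06 (SD, n = 3, limma adjusted p = 1.84e-11). Cxcl2, a neutrophil chemokine, rose 63.7-fold, Il1b 54.4-fold and Cxcl5 51.5-fold. The acute phase gene Saa3 rose 56.1-fold, the myeloid receptor Trem1 41.7-fold, and the stromelysin Mmp3 31.7-fold. Krtap4-7, which codes for a protein of the hair shaft, fell by 4.92 ± 0.32 (SE), and Krtap5-4 fell by 4.70 ± 0.32. Among hair keratins, Krt31 fell by 4.22 ± 0.19, Krt32 by 4.10 ± 0.17 and Krt35 by 4.09 ± 0.17. Gprc5d, a receptor gene of hair-forming cells, fell by 4.34 ± 0.28. Akr1c21, a steroid-converting enzyme, fell by 4.47 ± 0.22.

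Of 17 inflammatory cytokines and chemokines, 15 rose by day 3 and 2 did not pass (15 adjusted over the list alone, camera adjusted p = 3.54e-12, and adjusted p = 0.0241 with an estimated correlation). Macrophage markers rose in 12 of 13 members (12 adjusted over the list alone, adjusted p = 0.0241 with an estimated correlation), among them Chil3 by 4.94 ± 0.34, Arg1 by 2.90 ± 0.27 and Msr1, a scavenger receptor, by 2.54 ± 0.18. Neutrophil markers rose in 7 of 10 (8 adjusted over the list alone, adjusted p = 0.0944 with an estimated correlation), S100a9 by 5.23 ± 0.69 and the growth factor receptor Csf3r by 4.12 ± 0.21. Cell cycle genes rose in 21 of 22 (21 adjusted over the list alone, adjusted p = 0.0632 with an estimated correlation), such as Bub1 by 1.40 ± 0.16 and Top2a by 0.96 ± 0.14. Of 15 metalloproteinases and inhibitors, 11 rose and 2 fell (14 adjusted over the list alone, adjusted p = 0.0944 with an estimated correlation), Timp1 rising by 4.14 ± 0.20. Interferon response genes rose in 11 of 14 (11 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation), Ifit1 by 2.30 ± 0.40. Adipocyte markers fell in 8 of 9 (8 adjusted over the list alone, adjusted p = 0.142 with an estimated correlation), the hormone adiponectin, Adipoq, by 1.46 ± 0.30.

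Hair and nail keratins fell in 14 of 14 members by day 3 in B6 (14 adjusted over the list alone, adjusted p = 0.0288 with an estimated correlation). Of 14 hair follicle genes that are not keratins, a list chosen after the data were seen, 14 fell by day 3, and 14 by day 7 (camera with an estimated correlation, p = 0.00369 and 0.00236). At day 14, 7 of them were below day 0 (camera with an estimated correlation, p = 0.186). Keratin-associated proteins, which crosslink hair keratins, fell in 17 of 18 (17 adjusted over the list alone, adjusted p = 0.0772 with an estimated correlation). Among all 36 keratins, a list named by the series and so not independent evidence, 25 fell and 1 rose (28 adjusted over the list alone, adjusted p = 0.0632 with an estimated correlation). The one that rose was Krt16, a keratin of wounded epidermis, by 3.58 ± 0.58. Of 19 digit tip and blastema regulators, 13 fell, 3 rose and 3 did not pass (17 adjusted over the list alone, adjusted p = 0.511 with an estimated correlation), with Msx2 down by 2.32 ± 0.19 and Lef1 by 1.72 ± 0.13. Msx2, Lef1 and Foxn1 are also among the 14 hair follicle genes above, so their fall is counted in both lists. In total, 7234 of the 15928 probe sets differed between day 3 and day 0 in B6, 2776 higher and 4458 lower, and 1013 by at least 2-fold. The split moved with the scaling, to 3594 higher and 3459 lower after cyclic loess.

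At day 7 in B6, several proteases and most genes of fibrillar collagens and matrix stood above day 0, and hair keratins were still low. Mmp13 rose 64.6-fold against day 0, from 6.01 ± 0.31 to 12.02 ± 0.13 (SD, n = 3, limma adjusted p = 3.75e-11), and the gelatinase Mmp9 rose 28.4-fold. Atp6v0d2, a proton pump subunit of osteoclasts, the cells that resorb bone, rose 21.7-fold. Ctsk, a collagen-degrading protease of the same cells, rose by 2.82 ± 0.16 and Acp5 by 2.31 ± 0.17. Osteoclast markers rose in 8 of 10 members (8 adjusted over the list alone, adjusted p = 0.103 with an estimated correlation). Genes of fibrillar collagens and matrix rose in 20 of 21 (20 adjusted over the list alone, adjusted p = 0.103 with an estimated correlation), among them the wound matrix gene Tnc by 2.57 ± 0.11, the proteoglycan Lum by 1.97 ± 0.14 and Col12a1 by 1.87 ± 0.11. Of 15 metalloproteinases and inhibitors, 12 rose and 1 fell (14 adjusted over the list alone, adjusted p = 0.0612 with an estimated correlation).

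Inflammatory genes were above day 0 in 10 of 17 members at day 7 (10 adjusted over the list alone, adjusted p = 0.103 with an estimated correlation), and macrophage markers in 11 of 13 (12 adjusted over the list alone, adjusted p = 0.0612 with an estimated correlation). Cxcl5 was still 24.0-fold and Ccl3 18.9-fold above day 0. The hair and nail keratins had fallen in 14 of 14 (14 adjusted over the list alone, adjusted p = 0.0359 with an estimated correlation), Krt31 by 4.24 ± 0.19 and Krt27, a keratin of the inner root sheath, by 3.92 ± 0.27. Keratin-associated proteins had fallen in 17 of 18 (17 adjusted over the list alone, adjusted p = 0.0612 with an estimated correlation), Krtap5-4 by 5.23 ± 0.32 and Krtap26-1 by 4.81 ± 0.24. In all, 6838 probe sets differed, 3743 higher and 3095 lower, and 927 by at least 2-fold.

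At day 14 in B6, the bone genes Ibsp, Phex and Dmp1 and the proteases Mmp13 and Mmp9 stood above day 0, and most hair keratins did not pass the test against day 0. Ibsp, bone sialoprotein, rose 19.3-fold, from 7.91 ± 0.27 to 12.18 ± 0.41 (SD, n = 3, limma adjusted p = 8.05e-09). Mmp13 was 50.5-fold and Mmp9 20.2-fold above day 0, and C1qtnf3, a gene of developing cartilage, rose 15.1-fold. Of 9 osteoblast and osteocyte markers, 6 rose and 1 fell (7 adjusted over the list alone, adjusted p = 0.388 with an estimated correlation), with Phex up by 2.46 ± 0.26, the osteocyte gene Dmp1 by 1.78 ± 0.28 and Alpl by 1.41 ± 0.22. Of 13 cartilage markers, 7 rose and 1 fell (8 adjusted over the list alone, adjusted p = 0.543 with an estimated correlation), Col10a1 rising by 2.38 ± 0.36 and the proteoglycan Acan by 1.80 ± 0.23. Fibrillar collagens and matrix genes had risen in 20 of 21 members (20 adjusted over the list alone, adjusted p = 0.262 with an estimated correlation), Lum by 2.05 ± 0.14. Osteoclast markers were up in 6 of 10 (6 adjusted over the list alone, adjusted p = 0.317 with an estimated correlation), Ctsk by 2.42 ± 0.16.

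At day 14 in B6, 3 of 14 hair and nail keratins were below day 0, Krt31 by 0.93 ± 0.19 among them, and the other 11 did not pass (1 adjusted over the list alone, adjusted p = 0.496 with an estimated correlation). Of all 36 keratins, 11 were lower and 1 higher (9 adjusted over the list alone, adjusted p = 0.317 with an estimated correlation), with Krt15, a keratin of hair follicle stem cells, lower by 1.18 ± 0.12. Angptl7 fell by 2.50 ± 0.31, the methyltransferase Inmt by 2.48 ± 0.29 and Alas2, the heme synthesis enzyme of red cells, by 2.16 ± 0.32. In all, 5890 probe sets differed, 3624 higher and 2266 lower, and 645 by at least 2-fold. After cyclic loess the split was 3431 higher and 3227 lower.

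At day 7, MRL digits had more transcripts of hair keratins and of some cartilage genes than B6 digits, and fewer of macrophage and osteoclast markers and of some inflammatory genes. Krt31 was 1.64 ± 0.19 higher in MRL (SE, limma adjusted p = 9.57e-06), at 8.01 ± 0.06 against 6.36 ± 0.40 (SD, n = 3). Krt84, a keratin of nail and tongue, was 2.44 ± 0.46 higher, Krt27 1.54 ± 0.27 and Krt71, another keratin of the inner root sheath, 1.54 ± 0.27. Matn3, a cartilage matrix protein, was 2.56 ± 0.40 higher, at 8.81 ± 0.73 against 6.24 ± 0.20. Cxcl2 was 7.19-fold lower, the macrophage gene Chil3 6.25-fold, and Epgn, an epidermal growth factor family member, 7.34-fold.

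Of the 14 hair and nail keratins, 13 were higher in MRL and the other 1 did not pass (14 adjusted over the list alone, camera adjusted p = 1.82e-27, and adjusted p = 0.00530 with an estimated correlation). Keratin-associated proteins were higher in 16 of 18 (18 adjusted over the list alone, adjusted p = 0.00578 with an estimated correlation), Krtap1-5 14.4-fold and Krtap6-2 10.7-fold. Among all 36 keratins, the list that the series names and so not independent evidence, 13 were higher and 4 lower (21 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation), with a mean of 0.47 and a median of 0.09. Krt17, a keratin of wounded skin and of hair follicles, was lower at -0.75 ± 0.15 and the basal keratin Krt14 at -0.51 ± 0.10. Krt16 was also lower, at -2.49 ± 0.58, a call lost without MRL replicate 3 of day 7. Cartilage markers were higher in 8 of 13 (9 adjusted over the list alone, adjusted p = 0.0626 with an estimated correlation), among them Cnmd by 2.00 ± 0.32, the link protein Hapln1 by 1.79 ± 0.26 and Col9a1 by 1.74 ± 0.18.

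Macrophage markers were lower in MRL in 9 of 13 members at day 7 (12 adjusted over the list alone, adjusted p = 0.0119 with an estimated correlation), Arg1 at -2.18 ± 0.27 and the complement gene C1qb at -0.80 ± 0.14. Osteoclast markers were lower in 8 of 10 (8 adjusted over the list alone, adjusted p = 0.0480 with an estimated correlation), with Atp6v0d2 at -1.85 ± 0.25, the cell fusion gene Dcstamp at -1.77 ± 0.18 and Oscar at -1.55 ± 0.09. Inflammatory genes were lower in 10 of 17 (11 adjusted over the list alone, adjusted p = 0.0746 with an estimated correlation), Ccl3 at -2.42 ± 0.36 and Cxcl5 at -1.57 ± 0.35. Metalloproteinases and inhibitors were lower in 6 of 15 (7 adjusted over the list alone, adjusted p = 0.268 with an estimated correlation), Mmp9 at -1.51 ± 0.22 and Mmp3 at -1.06 ± 0.23. H2-Ea was higher in MRL, at 11.13 ± 0.06 against 5.26 ± 0.26 in B6, and Serpina3a, a serine protease inhibitor, at 9.03 ± 0.41 against 5.59 ± 0.43. Skint9 and Skint3, of a gene family that shapes T cells of the epidermis, were lower, at 2.74 ± 0.09 against 9.69 ± 0.18 and 3.12 ± 0.05 against 9.35 ± 0.09, as was Akr1c21, at 3.68 ± 0.33 against 7.56 ± 0.17. In all, 1506 probe sets differed, 507 higher and 999 lower in MRL, and 239 by at least 2-fold, with 1022 higher and 966 lower after cyclic loess. The count was 894 without MRL replicate 1 of day 7, 927 and 989 without B6 replicates 2 and 3, and 3107 with array weights.

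**Figure D3:**
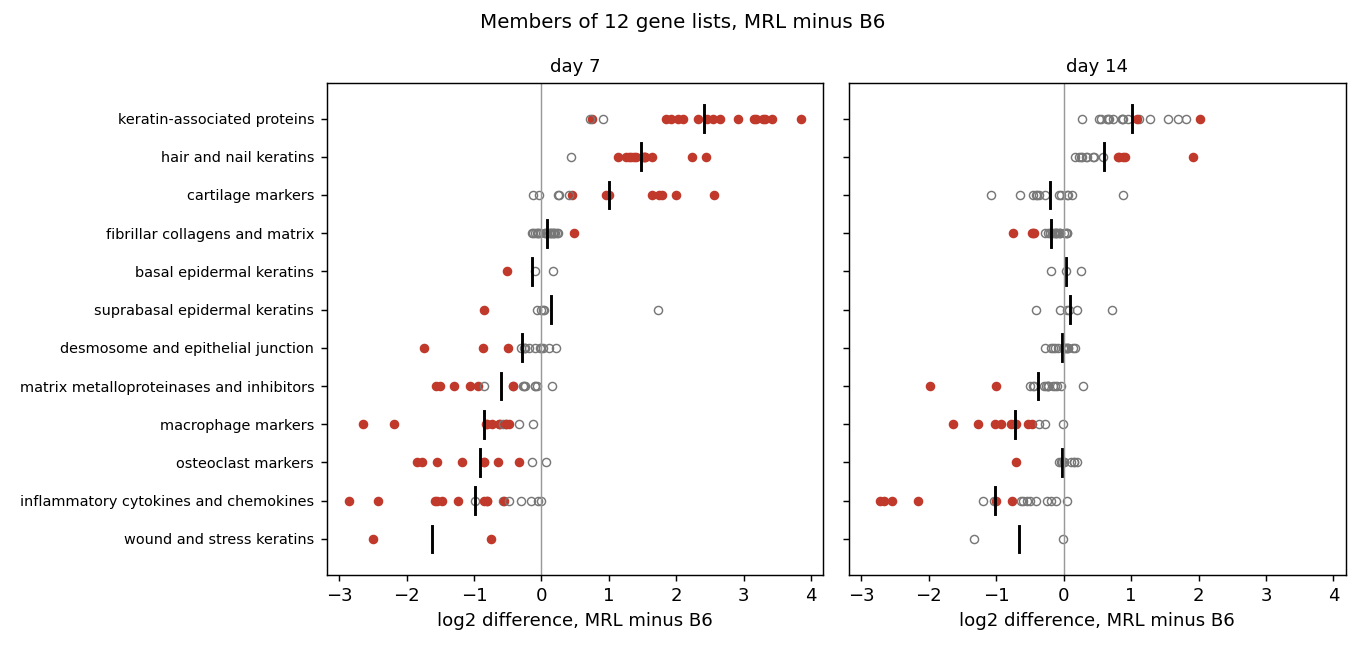
Log2 difference, MRL minus B6, of each measured member of 12 gene lists at day 7 and day 14. Filled points passed the test (limma, adjusted p under 0.05), open points did not, and black bars mark the list mean. Hair and nail keratins had a mean of 1.48 at day 7 and 0.60 at day 14, and macrophage markers of -0.85 and -0.73.

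At day 14, macrophage markers were lower in MRL than in B6, as were some inflammatory and interferon genes. Il1b was 6.31-fold lower, at 6.90 ± 0.47 in MRL and 9.56 ± 0.08 in B6 (SD, n = 3, limma adjusted p = 4.05e-05). Cxcl2 was 6.59-fold lower, Cxcl5 5.82-fold and Ifit1, an interferon-induced gene, 5.66-fold. Macrophage markers were lower in 10 of 13 members (12 adjusted over the list alone, adjusted p = 0.0209 with an estimated correlation), among them Chil3 at -1.65 ± 0.34, the surface protein Adgre1 at -1.01 ± 0.19 and C1qb at -0.93 ± 0.14. Inflammatory genes were lower in 6 of 17 (10 adjusted over the list alone, adjusted p = 0.0766 with an estimated correlation), Ccl3 at -2.15 ± 0.36. Interferon response genes were lower in 6 of 14 (9 adjusted over the list alone, adjusted p = 0.219 with an estimated correlation), Ifit2 at -1.30 ± 0.16 and Oasl2 at -1.26 ± 0.22. Of 5 genes of MHC class II presentation, 3 were lower (4 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation), H2-Ab1 at -1.43 ± 0.17 and H2-Aa at -0.72 ± 0.12. H2-Ab1 was lower on all 4 days, from -1.53 to -1.23, so its difference is not particular to day 14. Whether probes designed on the reference strain bind MRL transcripts of these genes less well was not tested.

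At day 14, 5 of 14 hair and nail keratins were higher in MRL (8 adjusted over the list alone, adjusted p = 0.0766 with an estimated correlation), such as Krt39 by 0.88 ± 0.19 and Krt74 by 0.82 ± 0.18. Keratin-associated proteins were higher in 2 of 18 (11 adjusted over the list alone, adjusted p = 0.0766 with an estimated correlation). Among all 36 keratins, 5 were higher (7 adjusted over the list alone, adjusted p = 0.140 with an estimated correlation), with a mean of 0.24. Gsta4, a glutathione transferase, was 4.28-fold higher in MRL. H2-Ea was higher, at 10.73 ± 0.15 against 5.17 ± 0.51 in B6, and Skint9 and Skint3 were lower, at 2.88 ± 0.07 against 9.86 ± 0.21 and 3.11 ± 0.22 against 9.34 ± 0.30. In all, 839 probe sets differed, 138 higher and 701 lower, and 137 by at least 2-fold, with 384 higher and 635 lower after cyclic loess. The count was 499 without MRL replicate 2, 518 without B6 replicate 2 and 1177 without MRL replicate 3. It was 424 in a fit of the compared arrays alone and 2912 with array weights. No test compared this count with that of day 7.

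As labelled, MRL digits before amputation had more transcripts of most inflammatory genes and fewer of most hair keratins than B6 digits. Saa3 was 5.18 ± 0.42 higher in the arrays labelled MRL day 0 than in B6 day 0 (SE, n = 3, limma adjusted p = 1.05e-08), Cxcl5 4.92 ± 0.35 and Mmp13 4.53 ± 0.34 higher, and Krt31 was lower at -3.12 ± 0.19. Inflammatory genes were higher in 13 of 17 members (14 adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation). Lower levels were found for 13 of 14 hair and nail keratins (13 adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation). Over all 36 keratins, 20 were lower and 1 higher (21 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation), with a mean of -0.89. In all, 6372 probe sets differed, 2850 higher and 3522 lower. With the arrays labelled MRL day 3 in their place, a contrast added after the values were seen, 4833 differed from B6 day 0 and the keratin mean was 0.10 (camera adjusted p = 0.877), with 1 of 14 hair and nail keratins higher (1 adjusted over the list alone).

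At day 3 as labelled, the direction was the opposite. Cxcl2 was lower in the arrays labelled MRL day 3 than in B6 day 3, at -6.32 ± 0.44 (SE, n = 3, limma adjusted p = 4.87e-10), Il1b at -5.79 ± 0.35 and Mmp13 at -5.17 ± 0.34, and Krt32, a keratin of the hair cuticle, was 4.01 ± 0.17 higher. Inflammatory genes were lower in 15 of 17 members (16 adjusted over the list alone, adjusted p = 0.0146 with an estimated correlation), and macrophage markers in 12 of 13 (12 adjusted over the list alone, adjusted p = 0.00730 with an estimated correlation). The hair and nail keratins were higher in 14 of 14 (14 adjusted over the list alone, adjusted p = 0.0230 with an estimated correlation), and over all 36 keratins, 25 were higher and 1 lower (26 adjusted over the list alone, adjusted p = 0.0630 with an estimated correlation), with a mean of 1.56. In all, 6474 probe sets differed, 4311 higher and 2163 lower, and after cyclic loess 3015 were higher and 3356 lower. With the arrays labelled MRL day 0 in their place, 1741 differed from B6 day 3, and 13 of 14 hair and nail keratins were higher (14 adjusted over the list alone, adjusted p = 0.112 with an estimated correlation).

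Within MRL as labelled, inflammatory genes fell and hair keratins rose by day 3. Cxcl2 fell by 4.81 ± 0.44 (SE, n = 3, limma adjusted p = 9.66e-08), Mmp13 by 4.72 ± 0.34 and Timp1, an inhibitor of matrix proteases, by 3.84 ± 0.20. Krt32 rose by 2.78 ± 0.17 and Krt35 by 2.74 ± 0.17. As labelled, 13 of 14 hair and nail keratins rose (13 adjusted over the list alone, adjusted p = 0.0132 with an estimated correlation). Inflammatory genes fell in 13 of 17 (13 adjusted over the list alone, adjusted p = 0.0132 with an estimated correlation) and macrophage markers in 12 of 13 (12 adjusted over the list alone, adjusted p = 0.00261 with an estimated correlation). In all, 3267 probe sets differed, 2128 higher and 1139 lower, and after cyclic loess 1503 were higher and 1722 lower. With these 2 groups in each other's place, each of these changes has the opposite sign. The count was 2113 without replicate 1 of the arrays labelled MRL day 3.

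At day 7 against the arrays labelled MRL day 0, cartilage and matrix genes were higher in MRL. Matn3 rose by 3.37 ± 0.40 (SE, n = 3, limma adjusted p = 4.13e-06), Col11a1 by 3.23 ± 0.19 and Acan, the main proteoglycan of cartilage, by 3.14 ± 0.23. Cartilage markers rose in 11 of 13 members (11 adjusted over the list alone, adjusted p = 0.0418 with an estimated correlation), and fibrillar collagens and matrix genes in 17 of 21 (19 adjusted over the list alone, adjusted p = 0.0418 with an estimated correlation). Tendon markers rose in 4 of 5 (4 adjusted over the list alone, adjusted p = 0.0418 with an estimated correlation), the transcription factor Scx by 2.54 ± 0.20. Inflammatory genes fell in 13 of 17 (13 adjusted over the list alone, adjusted p = 0.0418 with an estimated correlation), Ccl3 by 2.85 ± 0.36. In all, 2753 probe sets differed, 1709 higher and 1044 lower. Against the arrays labelled MRL day 3, 13 of 14 hair and nail keratins were lower at day 7 (13 adjusted over the list alone, adjusted p = 0.0267 with an estimated correlation), and inflammatory genes were higher in 5 and lower in 2 of 17 (7 adjusted over the list alone, adjusted p = 0.283 with an estimated correlation). The count was 1738 without MRL replicate 3 of day 7 and 4639 with array weights.

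At day 14 against the same arrays, hair keratins and some bone genes were higher. Krt32 rose by 3.11 ± 0.17 (SE, n = 3, limma adjusted p = 9.74e-11), Col10a1, a collagen of mineralising cartilage, by 3.23 ± 0.36 and Phex, an endopeptidase of osteoblasts and osteocytes, by 2.97 ± 0.26. Hair and nail keratins rose in 13 of 14 members (13 adjusted over the list alone, adjusted p = 0.00870 with an estimated correlation) and keratin-associated proteins in 17 of 18 (18 adjusted over the list alone, adjusted p = 0.0137 with an estimated correlation). Osteoblast and osteocyte markers rose in 6 of 9 (7 adjusted over the list alone, adjusted p = 0.0768 with an estimated correlation). Cell cycle genes fell in 19 of 22 (20 adjusted over the list alone, adjusted p = 0.0303 with an estimated correlation), Mcm5 by 0.83 ± 0.15. In all, 2818 probe sets differed, 1667 higher and 1151 lower. Against the arrays labelled MRL day 3, 1 of 14 hair and nail keratins was higher at day 14 (0 adjusted over the list alone, adjusted p = 0.405 with an estimated correlation), and 2 of 22 cell cycle genes were lower (2 adjusted over the list alone, adjusted p = 0.390 with an estimated correlation). The count was 5735 with array weights and 1729 in a fit of the compared arrays alone.

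The change from day 0 was then compared between the strains, again as labelled. At day 3 the difference between the changes, MRL minus B6, was -10.81 ± 0.63 for Cxcl2 (SE, n = 3 per group, limma adjusted p = 1.60e-11) and 6.87 ± 0.27 for Krt31. The hair and nail keratins had a mean difference of 5.33 with 14 of 14 members higher (14 adjusted over the list alone, adjusted p = 0.0256 with an estimated correlation), and inflammatory genes were lower in 16 of 17 (16 adjusted over the list alone, adjusted p = 0.0134 with an estimated correlation). Among all 36 keratins, again not independent evidence, 23 were higher and 1 lower (27 adjusted over the list alone, adjusted p = 0.0602 with an estimated correlation), with a mean of 2.45. In all, 7200 probe sets differed, 4585 higher and 2615 lower. The median of all probe sets was itself 0.12, and cyclic loess gave 3457 higher and 3553 lower. With the groups labelled MRL day 0 and MRL day 3 set in each other's place, the count was 1577 and the keratin mean 0.46. In that setting, 10 of 14 hair and nail keratins were higher with a mean of 1.11 (12 adjusted over the list alone, adjusted p = 0.361 with an estimated correlation). Of 17 inflammatory genes, 6 were lower and Ccl8 was higher by 1.84 ± 0.39 (9 adjusted over the list alone, adjusted p = 0.361 with an estimated correlation).

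At day 7 the same comparison gave -5.49 ± 0.82 for Krt16 (SE, n = 3 per group, limma adjusted p = 3.82e-05) and 4.76 ± 0.27 for Krt31. For hair and nail keratins the mean was 3.56, 13 of 14 being higher (14 adjusted over the list alone, adjusted p = 0.0147 with an estimated correlation), and keratin-associated proteins were higher in 17 of 18 (17 adjusted over the list alone, adjusted p = 0.0243 with an estimated correlation). Inflammatory genes were lower in 13 of 17 (15 adjusted over the list alone, adjusted p = 0.0250 with an estimated correlation). Over the whole keratin list of 36, 18 were higher and 4 lower (24 adjusted over the list alone, adjusted p = 0.102 with an estimated correlation), with a mean of 1.36. In all, 4962 probe sets differed, 2220 higher and 2742 lower, and after cyclic loess 2880 were higher and 2698 lower. With the 2 MRL groups in each other's place, the keratin mean was 0.36. In that setting, 12 of 14 hair and nail keratins were higher with a mean of 1.45 (12 adjusted over the list alone, adjusted p = 0.0852 with an estimated correlation), and 7 of 17 inflammatory genes were lower (10 adjusted over the list alone, adjusted p = 0.455 with an estimated correlation).

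At day 14 it gave -7.46 ± 0.49 for Cxcl5 (SE, n = 3 per group, limma adjusted p = 1.60e-09) and 3.93 ± 0.27 for Krt31. For hair and nail keratins the mean was 2.68, with 13 of 14 higher (13 adjusted over the list alone, adjusted p = 0.0213 with an estimated correlation), and inflammatory genes were lower in 14 of 17 (14 adjusted over the list alone, adjusted p = 0.0304 with an estimated correlation). Over the whole keratin list of 36, 18 were higher and 1 lower (19 adjusted over the list alone, adjusted p = 0.0506 with an estimated correlation), with a mean of 1.13. In all, 4251 probe sets differed, 1767 higher and 2484 lower, and after cyclic loess 2511 were higher and 2486 lower. With the 2 MRL groups in each other's place, the keratin mean was 0.13. In that setting, 3 of 14 hair and nail keratins were higher with a mean of 0.57 (3 adjusted over the list alone, adjusted p = 0.698 with an estimated correlation), and 6 of 17 inflammatory genes were lower (6 adjusted over the list alone, adjusted p = 0.698 with an estimated correlation).

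Amputated digits as labelled were last set against unamputated ones over both strains. C1qtnf3 rose by 2.29 ± 0.11 (SE, n = 3 per group, limma adjusted p = 4.25e-11), Mmp13 by 2.26 ± 0.20, Ibsp by 2.21 ± 0.19 and Col10a1 by 2.06 ± 0.21. These are means over both strains, which did not always change alike. Mmp13 rose by 5.55 ± 0.28 in B6 alone. In MRL its levels as labelled were 10.54 at day 0, then 5.82, 10.72 and 11.96. Fibrillar collagens and matrix genes rose in 19 of 21 members (20 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation), Lum by 1.13 ± 0.08. Metalloproteinases and inhibitors rose in 9 of 15 (9 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation) and osteoclast markers in 6 of 10 (7 adjusted over the list alone, adjusted p = 0.279 with an estimated correlation), Ctsk by 1.36 ± 0.10. Of all 36 keratins, 20 fell (22 adjusted over the list alone, adjusted p = 0.279 with an estimated correlation), Krt15 by 0.47 ± 0.07. Akr1c21 fell by 1.37 ± 0.12. In MRL it was low on every labelled day, at 4.14, 4.43, 3.68 and 3.84, against 9.25 in B6 day 0. In all, 5383 probe sets differed, 3267 higher and 2116 lower, 53 by at least 2-fold. In B6 alone, 7811 differed, 687 by at least 2-fold.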

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

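The tests on the day labels, those on the probe sets apart on all days, that on the amount of skin and the sorting of splits by whether they mixed the strains on both days were chosen only after the result was seen, as were the comparisons that put the groups labelled MRL day 0 and MRL day 3 against other groups and those of day 14 with day 7.

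The strains differed in the change from day 0, by a test of that difference, for 7200 probe sets at day 3, 4962 at day 7 and 4251 at day 14. As many were found in 1, 1 and 4 of 100 splits of the arrays, the real one included. These splits exchanged arrays between the strains within each day. They stand for no strain difference on a day, not for an equal change in both strains, so the share does not decide on the change. The highest others, 4556, 4244 and 5047, left the real strains of a day whole, and splits that mixed the strains on both days gave at most 0, 1 and 1. Hair and nail keratins differed in this change by a mean of 5.33, 3.56 and 2.68, and by 1.11, 1.45 and 0.57 with the groups labelled MRL day 0 and MRL day 3 in each other's place. All keratins differed by 2.45, 1.36 and 1.13, a shift that 1 of 100 splits reached on each day, against 1.95, 1.18 and 1.12 in the highest other. Each of these values rests on the arrays labelled MRL day 0 or MRL day 3, whose day labels are in doubt.

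From day 7 to day 14, which needs none of those arrays, the strains differed in the change of 42 probe sets. As many came from 14 of 100 splits, the real one included, and the highest other gave 1653. The other 13 of these splits left the real strains of a day whole, and with them its strain difference, so this share does not decide on chance. The 76 splits that mixed the strains on both days gave at most 2. Over the 733 probe sets with no gene symbol, which the comparisons left out, 87 differed between the strains at day 7 and 36 at day 14 (limma, adjusted over all 16661 probe sets).

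Amputated against unamputated digits as labelled, 5383 probe sets differed over both strains and 7811 in B6 alone. Only 1 of 100 splits gave as many in each case, the real one, and the highest others were 2146 and 4112. These splits moved arrays among all days of a strain, so they stand for no difference between any of the days. Differences among days 3, 7 and 14 then add to the spread of the other splits. The share therefore speaks against a random grouping of the arrays by day, and does not decide on amputated against unamputated digits alone. Over both strains the share also does not tell whether the arrays labelled MRL day 0 and MRL day 3 carry the right labels. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and the real one gave the highest value in each comparison. Between the strains the real split gave 6372, 6474, 1506 and 839 probe sets at days 0, 3, 7 and 14, and the highest other 0, 0, 0 and 1. Against day 0 in B6 it gave 7234, 6838 and 5890 at days 3, 7 and 14, and the highest other 2, 0 and 0. In MRL it gave 3267, 2753 and 2818, with 0, 0 and 0 in the highest others. For the arrays labelled MRL day 3 against B6 day 0 it gave 4833 (highest other 0), and for those labelled MRL day 0 against B6 day 3 1741 (16). The keratin shift between the strains was -0.89, 1.56, 0.47 and 0.24 on the 4 days, and the largest other in size 0.39, 0.63, 0.29 and 0.22.

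The arrays labelled MRL day 0 lay 0.596 further toward B6 day 3 than those labelled MRL day 3, on the axis from B6 day 0 (0) to B6 day 3 (1). A single array with a wrong label was argued against, since 3 of 3 arrays labelled MRL day 0 lay beyond the midpoint. An exchange of arrays between the strains was argued against as well, since 0 of 12 arrays lay on the other strain's side over 13 strain genes. With these 2 groups in each other's place, 4833 probe sets still differed between MRL and B6 at day 0, against 6372 as labelled. The strain counts at days 7 and 14 were 1506 and 839, and the cause of this surplus was not tested. An exchange of the day labels of these 2 groups is a candidate explanation that has the values it needs on this axis. Correct labels would need an unamputated MRL digit that carried the profile of an amputated one. That profile would be lost by day 3, at a mean of 0.140, and partly back at day 7, at 0.501. With the 2 groups in each other's place, the MRL means run 0.140, 0.736, 0.501 and 0.262. B6 ran 0.00822, 0.988, 0.745 and 0.442, also a rise and then a decline. Since each label has 1 group of arrays, the 2 accounts cannot be told apart for certain.

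On all 4 days, 20 probe sets were at least 2-fold apart between the strains, 7 higher in MRL, among them H2-Ea and B4galnt2, a glycosyltransferase gene, and 13 lower, among them Skint9, Skint3, Skint4 and the antioxidant gene Prdx2. Probes designed on the reference strain may bind MRL transcripts less well, and 65% were lower in MRL (95% exact interval 40.8 to 84.6, two-sided exact binomial p = 0.263), too few probe sets to tell. After cyclic loess 54.5% of 22 probe sets were lower, so scaling between arrays may account for part of the surplus of lower ones, on a small number of probe sets. H2-Ea is a gene that the B6 haplotype does not transcribe. For the others, a difference of the genes themselves between the strains stays open as well, and was not tested.

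Hair and nail keratins were higher in MRL at day 7 by a mean of 1.48 (SE 0.13 over genes). More skin in the MRL samples was argued against by 23 epidermal genes, which had a mean of -0.160 (SE 0.124 over genes, not over arrays). Of these, Dsc2 itself changed with time, lower by 1.26 ± 0.26 at day 14 than at day 7 in B6. The amount of skin is therefore not settled. More growing hair follicle tissue is a candidate explanation, by a list written after the data had been examined and so not independent evidence. Its 14 measured hair follicle genes that are not keratins had a mean of 0.620 (SE 0.155, camera p = 9.36e-13, and 0.00504 with an estimated correlation). Of these, 7 were higher, such as S100a3 by 2.11 ± 0.19 and Padi3, an enzyme of hair protein maturation, by 1.17 ± 0.14. In an earlier list, the digit tip and blastema regulators, were 3 of the genes, Lef1, Msx2 and Foxn1. Whether this was an uneven share of hairy skin taken with the digit or a faster return of hair growth in MRL was not tested, and a difference between the strains stays open.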

How the results depend on the processing

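Leaving out the arrays labelled MRL day 0 and MRL day 3, and setting these groups in each other's place, were chosen only after the result was seen. Array weights moved the counts of probe sets that differed to 3107 between the strains at day 7, 2912 at day 14, and 4639 and 5735 for days 7 and 14 against day 0 in MRL. The weights ran from 0.225 for MRL day 14 replicate 3 to 4.28 for MRL day 14 replicate 1. A fit of only the arrays compared gave 424 between the strains at day 14 and 1729 for day 14 against day 0 in MRL. It has fewer degrees of freedom. The other counts stayed within 1.5 times under each planned setting that kept all arrays of the comparison. The cause of the rise with array weights was not tested.

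With each array left out in turn, the strain count at day 7 ran from 894 (without MRL replicate 1) to 1297 (without B6 replicate 1), with 927 and 989 without B6 replicates 2 and 3. At day 14 it ran from 499 (without MRL replicate 2) to 1177 (without MRL replicate 3), with 518 without B6 replicate 2. For MRL against day 0 it ran from 2113 (without MRL day 3 replicate 1) to 2993 (without MRL day 0 replicate 1) at day 3, and from 1738 (without MRL day 7 replicate 3) to 2465 (without MRL day 0 replicate 2) at day 7. Fewer arrays were fitted in each case. With replicate number as a block, the number of probe sets called, MRL minus B6 at day 7, was 1436, and that of probe sets called, MRL minus B6 at day 14, was 787.

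With an estimated correlation the keratin shifts no longer passed, at -0.89, 1.56, 0.47 and 0.24 between the strains on days 0, 3, 7 and 14 (camera adjusted p = 0.137, 0.0630, 0.137 and 0.140). The same held for the differences in the change at days 3, 7 and 14, at 2.45, 1.36 and 1.13 (adjusted p = 0.0602, 0.102 and 0.0506). The shift is the same by construction, and the genes of the list vary together. Cyclic loess turned Krt10 and Krt5 between the strains at day 0 to -0.21 and -0.21, and Krt10 in the day 7 difference to 0.36; the cause was not tested. It moved the median of all probe sets by at most 0.12.

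With the groups labelled MRL day 0 and MRL day 3 in each other's place, the keratin shift at day 0 turned to 0.10, and 1741 probe sets differed between the strains at day 3 and 1577 in the day 3 difference, since other arrays are then compared. Without these 6 arrays the number of probe sets called, MRL minus B6 at day 7, was 1273, and that of probe sets called, MRL minus B6 at day 14, was 727. Of 1501 results for named genes that passed, 63 no longer passed after cyclic loess, 21 with array weights, 21 with the replicate block and 14 with a variance trend. Of those refitted with only the arrays compared, 69 no longer passed and 1319 did. Leaving out 1 array ended 761 calls and kept 12349. Signal over background was not analysed here, and the filter on dim probe sets kept 11936 of 15928.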

Other observations

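From day 7 to day 14, a comparison chosen only after the result was seen, hair shaft genes rose in both strains. In B6, Krtap5-4 rose 35.8-fold (limma adjusted p = 4.79e-10), Krtap26-1 28.6-fold and the hair cuticle keratin Krt32 by 3.87 ± 0.17 (SE, n = 3). Keratin-associated proteins rose in 17 of 18 members (18 adjusted over the list alone, adjusted p = 9.77e-05 with an estimated correlation) and hair and nail keratins in 13 of 14 (13 adjusted over the list alone, adjusted p = 2.25e-05 with an estimated correlation). Of 14 hair follicle genes that are not keratins, a list chosen after the data were seen, 12 rose, with a mean of 1.59 (camera with an estimated correlation, p = 6.84e-06). Phex, an endopeptidase of bone cells, rose by 2.64 ± 0.26 and Dmp1, an osteocyte gene, by 1.55 ± 0.28. Osteoclast markers fell in 4 of 10 (8 adjusted over the list alone, adjusted p = 0.0211 with an estimated correlation), Oscar by 0.94 ± 0.09 and Dcstamp by 0.95 ± 0.18. In all, 296 probe sets differed, 232 higher and 64 lower at day 14. Of 10 splits of the arrays, too few for a share under 0.05, the real one gave the most and the highest other 2.

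In MRL over the same days, several cartilage genes fell while hair shaft genes rose. Matn3, a cartilage matrix protein, fell by 2.82 ± 0.40 (SE, n = 3, limma adjusted p = 9.90e-05), the link protein gene Hapln1 by 2.16 ± 0.26 and Acan by 1.65 ± 0.23. Cartilage markers fell in 7 of 13 members (8 adjusted over the list alone, adjusted p = 0.114 with an estimated correlation). Genes of fibrillar collagens and matrix fell in 6 of 21 (12 adjusted over the list alone, adjusted p = 0.264 with an estimated correlation), Col12a1 by 0.89 ± 0.11. Scx, the transcription factor of tendon, fell by 1.26 ± 0.20. Hair and nail keratins rose in 13 of 14 (13 adjusted over the list alone, adjusted p = 3.53e-04 with an estimated correlation), Krt32 by 2.83 ± 0.17, and Phex rose by 1.93 ± 0.26. In all, 564 probe sets differed, 279 higher and 285 lower at day 14. Again with 10 splits, the highest other gave 0.

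The strains differed in this later change for several osteoclast and cartilage genes. Of 10 osteoclast markers, 5 were higher in the MRL change than in the B6 change (8 adjusted over the list alone, adjusted p = 0.00987 with an estimated correlation), Dcstamp by 1.72 ± 0.26 (SE, n = 3 per group, limma adjusted p = 0.00327). Of 13 cartilage markers, 7 were lower (9 adjusted over the list alone, adjusted p = 0.0429 with an estimated correlation), Matn3 at -3.64 ± 0.56 and Col9a1 at -2.01 ± 0.25.

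Between days 7 and 14 many of the same probe sets separated the strains. Of 507 higher in MRL at day 7 and 138 at day 14, 91 were shared, against 4.39 if the days were independent. Of 999 and 701 lower in MRL, 390 were shared, against 44.0. Both days use the same estimate of spread for each probe set, which alone can raise the overlap. The excess over independence was not tested. On the axis from B6 day 0 to B6 day 3, B6 had a mean position of 0.745 at day 7 and 0.442 at day 14, and MRL of 0.501 and 0.262.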
